A study of Mus musculus with 36 samples.

How the data were processed

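The authors deposited 36 scans of 2-colour Agilent 4x44k mouse arrays, 1 per animal, quantified with Agilent Feature Extraction 9.5.3.1 per the file headers, and a file of values per probe. Per the labels, 500 ng of total RNA of each animal was copied and labelled with both dyes, the Cy3 products were pooled in equal amounts, and each Cy5 product was hybridised with that pool. The intensity values used here were, per the file headers, the mean spot signal and the median local background of each channel on a linear scale, with no normalization. The processed intensity values, which the authors obtained with Feature Extraction by background subtraction, spatial detrending and linear and lowess dye normalization, were used as an alternative. The deposited series matrix holds log2 values for 22510 probes. They follow the Cy5 signal (r of at least 0.989 on each array) and not the ratio, and their medians per array lie between 9.26 and 9.29, so they are log2 Cy5 levels matched between arrays. How the authors made them is not given in the sources used here. All animals were hybridised in a single dye orientation, so a dye effect of a probe cancels between groups but was not measured. Probe coordinates are on mm8 (NCBI36) per the file headers.

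Each array held 45018 spots, 43379 of them not controls, for 41174 probes. Probes were named by the accession in the file where the mouse reference annotation knew it (24375 probes), else by a current symbol (6301), another accession (48) or a synonym (2391), and 8059 kept the name in the file. Background was corrected with the normexp method of limma (offset 50), ratios were normalised within arrays by loess with 4 iterations and control spots at weight 0, and no scaling between arrays was applied. Spots marked as non-uniform or as population outliers were left out, saturated spots were kept, and spots of a probe were averaged. A probe was kept if its Cy5 signal was well above background on at least 9 arrays of at least 1 group (24706 probes). Of each gene the probe with the highest mean intensity over all arrays was used, which gave 16500 genes. Of 5764 genes with several probes, probes that passed disagreed in sign for 398 genes between HF-DR and HF-AL, 0 between HF-AL and t0 and 310 between HF-DR and t0.

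The groups were compared with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), in 1 fit over all 36 arrays with a mean per group, moderated variances and Benjamini-Hochberg adjustment, two-sided. These choices, the gene lists, the rule for naming genes and most of the alternatives were fixed before the data were examined. The genes named were, per comparison, the 8 largest rises and 8 largest falls among changed genes with a curated symbol, a fixed set of 21 genes, up to 3 genes of each list with the smallest adjusted p and up to 1 further gene going the other way, and any of these again in the other comparisons. Some genes that the rule names are not reported here. Of the fixed set, Pck1 was not on the array and Ucp1 did not pass the filter. Genes of the male tract not covered by the rule, and the arrays they mark, were chosen after their values were seen.

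The 34 fixed lists covered fatty acid synthesis, triglyceride synthesis and storage, lipolysis, mitochondrial fatty acid oxidation, tricarboxylic acid cycle and pyruvate oxidation, mitochondrial respiratory chain, branched-chain amino acid catabolism, glucose uptake and glycolysis, insulin signalling, cholesterol synthesis, adipokines, fat mass expansion, collagens and extracellular matrix, chemokines and inflammatory cytokines, circadian clock, glucocorticoid-responsive genes, antioxidant and glutathione genes, unfolded protein response, brown and beige adipocyte genes and cell cycle. They also covered markers of mature adipocytes, preadipocytes and fibroblasts, macrophages, T and NK cells, B cells, mast cells, neutrophils, endothelium, smooth muscle and pericytes, mesothelium, epididymis and seminal vesicle, testis and sperm, skeletal muscle and red blood cells. Of these, 33 had at least 5 measured genes and were tested with camera in limma at a preset correlation of 0.01, adjusted over 99 tests. Camera with an estimated correlation and fry were run beside it. Missing values (0.302%) were filled for these tests. List means are used within slides, and medians elsewhere.

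The normexp correction did not work as planned on 10 arrays (t0 10 and 12, HF-AL 1, 8, 11 and 12, HF-DR 1, 2, 11 and 12). There, specks, spots with a net signal under -50 and down to -65198 (84 over all 36 arrays, some of them on 2 further arrays), gave normexp a background spread of more than 5 times that of the negative controls in at least 1 channel. On HF-DR 2 the Cy5 spread was 1279, and 1.00 without the specks. This compresses the ratios of dim genes on those arrays. The planned fit was kept for the results reported, and the fit without the specks, chosen after seeing the data, is given beside it. Other alternatives chosen after seeing the data left out the 10 arrays, left out arrays with tract transcripts (HF-DR 7, 8 and 9, HF-AL 5, 7 and 9), left out arrays with an odd background (t0 2 and 4, HF-DR 5 and 10), or took slide as a random block.

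The alternatives planned were no background subtraction, the processed signals, median centring in place of loess, ratios scaled between arrays, the Cy5 channel alone, the deposited series matrix, no filter, a filter on all 36 arrays, the mean over the probes of a gene, outlier spots kept, only the 2 groups compared, array weights, the replicate number as a block, slide as a fixed block, adjusted p under 0.01, at least 1.5-fold, and each array left out in turn. The 36 arrays lay on 21 slides, of which 3 held all groups, and were scanned on 1 day.

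Arrays within a group were checked for copies: r between animals was 0.358 to 0.800 in t0, 0.0420 to 0.886 in HF-AL and 0.198 to 0.931 in HF-DR, with 0 identical arrays. Arrays of different groups correlated negatively down to -0.436, which ratios to a pool of the same groups can give, and the labels state the dyes, so the direction was kept. The fit was tested on simulated data with 16500 genes, of which 50 were changed at each fold. At 1.25, 1.5, 2 and 4-fold it recovered 50%, 92%, 98% and 100% between HF-DR and HF-AL (7 false calls), 62%, 96%, 100% and 100% between HF-AL and t0 (8 false calls), and 68%, 96%, 98% and 100% between HF-DR and t0 (14 false calls). The simulated noise was independent between genes and had the same spread in all groups, so these rates need not hold for the real arrays. Correlations expected from a shared group were tested on simulated data and by splitting its animals between both comparisons. Food intake, body weight and other measures of the mice were not analysed here.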

Results

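Gene expression was measured in epididymal white adipose tissue, the fat depot beside the epididymis, of 36 adult male C57BL/6J mice. All mice were adapted for 3 weeks to a purified diet with 30% of its energy as fat, eaten ad libitum. A group of 12 mice, called t0, was killed at that point. Another 12 mice, HF-AL, ate the same diet ad libitum for 12 more weeks, and the last 12 mice, HF-DR, received it for 12 weeks on a restricted basis given in the labels as 70 energy percent. RNA of each mouse was hybridised in the red dye Cy5 to 1 Agilent array against a pool of all samples in the green dye Cy3. Each value below is therefore a log2 ratio of 1 animal to the pool, and differences between groups are differences of these ratios with n = 12 animals in each group. The share of probes with a Cy5 signal well above background ran from 44.6% on array HF-DR 5 to 86.3% on array t0 2, and the median Cy5 signal ran from 102 to 372. The number of arrays limits the precision of each difference. A gene counts as changed when its adjusted p in limma was under 0.05 among 16500 genes.

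The comparison of HF-DR with HF-AL asks how the fat depot differed after 12 weeks of a restricted high-fat diet. Time of killing and time since the last meal did not enter the comparison. Their effect cannot be told apart from that of the restriction here. Restricted mice had higher expression of genes of fatty acid and cholesterol synthesis, glycolysis, pyruvate oxidation and the respiratory chain. They had lower expression of collagen, fibroblast and macrophage genes. With an estimated correlation the adjusted p of these lists was 0.130 to 0.650. Among genes with a curated name the largest rise was that of Elovl6, which elongates long-chain fatty acids and whose probe lies on chr3 from 129630352 to 129630411 (mm8). Its log2 ratio to the pool was 2.16 ± 0.44 (SD, n = 12) in HF-DR and -2.94 ± 0.34 (SD, n = 12) in HF-AL, a 34.3-fold difference (limma, adjusted p = 1.5e-24). Npr3, the clearance receptor for natriuretic peptides, whose probe lies on chr15 from 11784966 to 11784907 (mm8, reverse strand), was 8.88-fold lower (adjusted p = 4.4e-14), at -2.87 ± 0.84 (SD, n = 12) in HF-DR and 0.28 ± 0.34 (SD, n = 12) in HF-AL.

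Other genes with large rises concern sugar and lipid handling. They included the fructose transporter Slc2a5 (log2 difference 4.28 ± 0.26 SE), the elongase Elovl3 (3.99 ± 0.24), the glycogen-targeting subunit Ppp1r3b (3.41 ± 0.19), Acly, which makes acetyl-CoA from citrate (3.27 ± 0.17), the lipid droplet gene Cidea (3.20 ± 0.18) and the lipase inhibitor Angptl8 (3.16 ± 0.10). The deepest falls beside Npr3 were in the interferon-inducible genes Ifi27 (-3.67 ± 0.14) and Ifi27l2a (-3.41 ± 0.16), in Sncg (-2.92 ± 0.14), the immunoglobulin heavy chain Ighm (-2.68 ± 0.17), Emp1 (-2.66 ± 0.15), the imprinted gene Plagl1 (-2.60 ± 0.15) and the lipase inhibitor Angptl4 (-2.57 ± 0.13). The adjusted p of each of these genes was at most 4.4e-14.

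**Figure D1:**
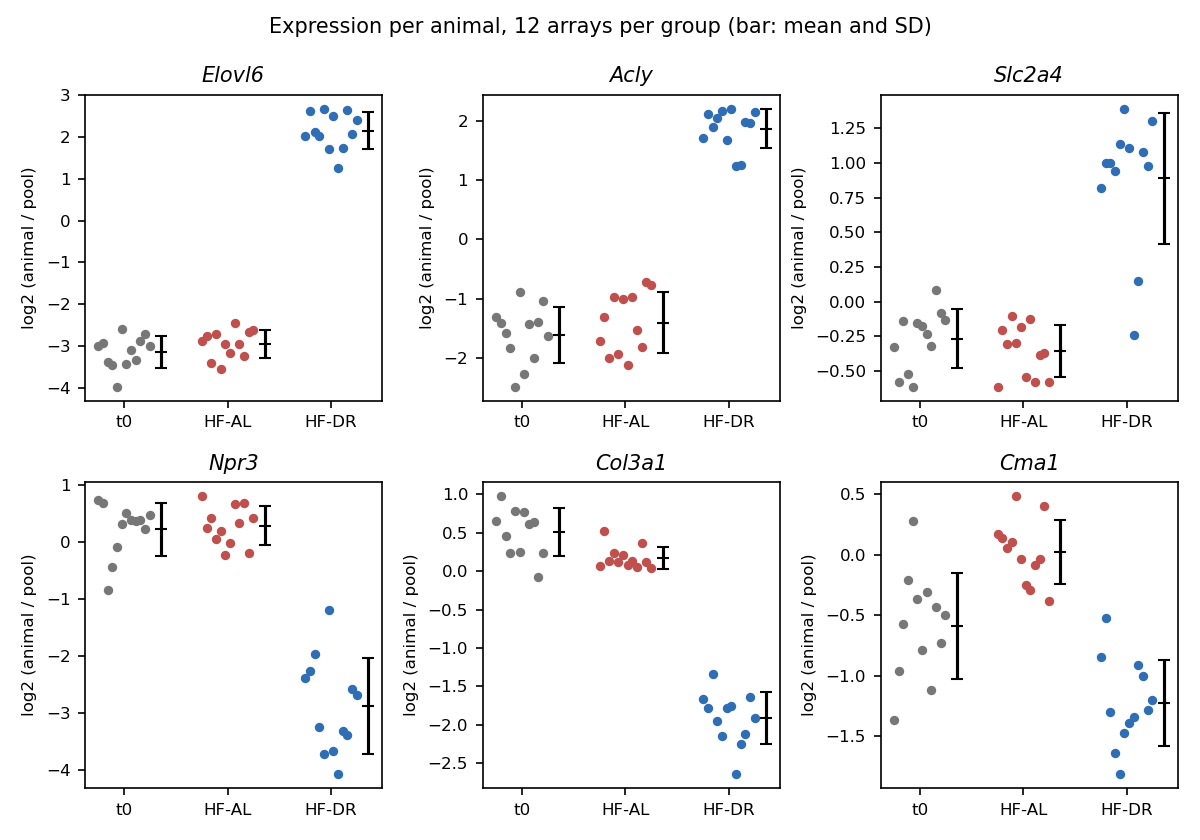
Log2 ratio to the pool of 6 genes in each animal (points, 12 per group), with bars for the group mean ± SD. Elovl6 separated HF-DR (mean 2.16) from HF-AL (-2.94) and t0 (-3.15) without overlap, while the mast cell protease Cma1 stood at -1.23, 0.02 and -0.59 in the same order.

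Of 24 fatty acid synthesis genes 21 rose and none fell, with a median log2 difference of 1.92 (camera with a preset correlation, adjusted p = 1.8e-16, and adjusted p = 0.130 with an estimated correlation). Beside Acly and Elovl6 these included Fasn (2.95 ± 0.20 SE), the malic enzyme Me1 (2.94 ± 0.15), the citrate carrier Slc25a1 (2.73 ± 0.13) and the desaturase Scd1 (1.23 ± 0.15). The Fasn probe was saturated on 6 of the 12 HF-DR arrays, so its difference is a lower bound. Of 22 cholesterol synthesis genes 21 rose, with a median of 1.51 (adjusted p = 8.7e-15, and adjusted p = 0.130 with an estimated correlation). Among them were Sqle (2.57 ± 0.13), Tm7sf2 (2.09 ± 0.10) and Fdft1 (1.45 ± 0.08). The exception was the regulator Srebf2 (-0.30 ± 0.09), which read 0.25 when its probes were averaged. Of 22 triglyceride synthesis and storage genes 11 rose and 4 fell, with a median of 0.47 (adjusted p = 0.0106, and adjusted p = 0.685 with an estimated correlation). Agpat2 (2.23 ± 0.13) and Gpd1 (1.67 ± 0.16), both on the path to triglyceride, rose, while the droplet coat gene Plin4 fell (-2.09 ± 0.14). These counts were the same adjusted over the list alone.

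Of 26 genes of the tricarboxylic acid cycle and pyruvate oxidation 25 rose, with a median of 0.76 (adjusted p = 2.3e-14, and adjusted p = 0.240 with an estimated correlation). The pyruvate carrier genes Mpc1 (2.48 ± 0.15 SE) and Mpc2 (1.84 ± 0.12) rose with the pyruvate dehydrogenase genes Pdha1 (1.93 ± 0.10) and Dlat (1.68 ± 0.10), and Idh2 fell (-0.44 ± 0.07). Of 51 respiratory chain genes 48 rose and none fell, with a median of 0.64 (adjusted p = 7.0e-19, and adjusted p = 0.244 with an estimated correlation). Cycs (1.38 ± 0.09), the ATP synthase gene Atp5pb (0.86 ± 0.06) and Cox7c (0.84 ± 0.07) were among them. In glucose uptake and glycolysis 14 of 18 genes rose and 1 fell, with a median of 0.78 (adjusted p = 8.2e-08, and adjusted p = 0.133 with an estimated correlation). Gapdh (1.45 ± 0.09), Pkm (1.27 ± 0.09), Pgk1 (1.21 ± 0.05) and the insulin-responsive glucose transporter Slc2a4 (2.37-fold) rose, and Hk1 fell (-0.48 ± 0.07). Mitochondrial fatty acid oxidation had 17 of 23 genes up and 2 down, with a median of 0.43 (adjusted p = 0.000179, and adjusted p = 0.631 with an estimated correlation). Of its entry enzymes, Cpt1b rose (0.97 ± 0.12) and Cpt1a fell (-0.77 ± 0.05). Branched-chain amino acid catabolism, with 11 of 21 genes up and 3 down, did not pass as a group by camera (adjusted p = 0.0780). The counts of these 5 lists were the same adjusted over the list alone.

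Brown and beige adipocyte genes had 10 of 14 up and 3 down, with a median of 0.98 (adjusted p = 0.000203, and adjusted p = 0.244 with an estimated correlation). Cox8b (2.76 ± 0.18 SE), the potassium channel Kcnk3 (1.57 ± 0.11) and the coactivator Ppargc1a (0.96 ± 0.14) rose, and the brown lineage factor Ebf2 fell (-0.84 ± 0.13). Ucp1 did not pass the signal filter and Pck1 was not on the array. Of 18 circadian clock genes 10 rose and 3 fell, with a median of 0.34 (adjusted p = 0.0381, and adjusted p = 0.590 with an estimated correlation). Nfil3 (1.75 ± 0.16) and Bhlhe40 (1.72 ± 0.17) rose, and Nr1d1 fell (-1.25 ± 0.16). Nr1d1 read -0.72 with slide as a block, and -1.99 to -0.18 on the 3 slides that held both groups. Adjusted over the list alone, these counts were the same.

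Genes tied to fat mass expansion fell in 5 of 6 cases, with a median of -1.23 (adjusted p = 0.0238, and adjusted p = 0.494 with an estimated correlation). The genes tied to fat mass expansion, HF-DR against HF-AL, had a mean of -0.99 and an adjusted p of 0.0975 with slide as a block. They included Npr3, Mest (-1.91 ± 0.28 SE), Bmp3 (-1.24 ± 0.22, and adjusted p = 0.0954 with slide as a block) and Sfrp5 (-0.48 ± 0.10). Leptin, whose transcript follows fat cell size, fell (Lep, -1.21 ± 0.23), and its adjusted p was 0.226 with slide as a block. Among 18 adipokine genes 3 rose and 9 fell. They did not pass by camera, which compares a list with the other genes tested (adjusted p = 0.397). By fry, which asks only whether a list moves 1 way on balance, they passed, down (adjusted p = 8.1e-05). Rarres2 (-2.27 ± 0.09) and Adipoq (-0.82 ± 0.13, and -0.54 with slide as a block) fell, and Apln (2.15 ± 0.16) and Nampt (1.06 ± 0.08) rose. Lipolysis genes went both ways, 6 of 19 up and 7 down (adjusted p = 0.997), with a median of -0.13, a mean of -0.04 and a test direction that was up. The triglyceride lipase Pnpla2 did not pass (0.07 ± 0.13, adjusted p = 0.663). Insulin signalling had 4 of 23 genes up and 8 down (adjusted p = 0.546 by camera, and 0.0283 by fry, down). Irs1 (-0.69 ± 0.10) and the receptor inhibitor Grb14 (-2.03 ± 0.18) were among the falls. The insulin signalling list also holds the pyruvate dehydrogenase kinase Pdk1, which rose (2.65 ± 0.11). Txnip, not of this list, fell (-1.42 ± 0.10). Of 19 mature adipocyte markers 3 rose and 11 fell, Plin1 among them (-0.90 ± 0.11, and -0.54 with slide as a block). The markers did not pass as a group by camera (adjusted p = 0.301) or by fry (adjusted p = 0.0661). Their mean was -0.25 on all arrays and 0.04 with slide as a block. The glucocorticoid-responsive genes had 4 of 15 up and 6 down (adjusted p = 0.338 by camera, and 1.0e-05 by fry, down). Of these genes Hsd11b1 rose (1.84 ± 0.13) and Fkbp5 did not pass (0.10 ± 0.16, adjusted p = 0.607). Adjusted over the list alone, the counts of these 6 lists were the same.

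Of 36 collagen and extracellular matrix genes 32 fell and 1 rose, with a median of -1.11 (adjusted p = 3.6e-11, and adjusted p = 0.244 with an estimated correlation). The fibrillar collagens Col3a1 (-2.09 ± 0.11 SE) and Col1a1 (-2.03 ± 0.10) fell, and Col12a1 rose (0.27 ± 0.09, but 0.13 and not passing with slide as a block). Preadipocyte and fibroblast markers fell in 17 of 19 cases, with a median of -0.72 (adjusted p = 2.9e-06, and adjusted p = 0.133 with an estimated correlation), led by Gsn (-2.10 ± 0.12). Of 28 macrophage markers 21 fell, with a median of -0.55 (adjusted p = 0.000179, and adjusted p = 0.650 with an estimated correlation), and adjusted over the list alone 21 fell and 1 rose. Lyz2 (-1.36 ± 0.14), Clec10a (-1.19 ± 0.13), the colony-stimulating factor receptor Csf1r (-0.93 ± 0.10), Adgre1 (-0.80 ± 0.13) and Itgax (-0.52 ± 0.10) were among them. Chemokines and inflammatory cytokines had 2 of 22 up and 8 down (1 up and 7 down adjusted over the list alone). Their adjusted p was 0.318 by camera and 0.000542 by fry, down. The monocyte attractant Ccl2 fell (-0.80 ± 0.23). The difference of Ccl2 HF-DR against HF-AL had an adjusted p of 0.0832 with slide as a block.

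Markers of other cells and processes did not pass as groups by camera in the planned fit between HF-DR and HF-AL. By fry, mesothelial (adjusted p = 3.0e-05), mast cell (6.9e-06) and endothelial markers (0.0135) passed, down. Neutrophil markers (adjusted p = 5.9e-05) and antioxidant and glutathione genes (0.00104) passed by fry too, up. Endothelial markers had 2 of 17 up and 10 down (adjusted p = 0.127), mesothelial markers 9 of 13 down (adjusted p = 0.0905), and smooth muscle and pericyte markers 2 of 12 up and 3 down (adjusted p = 0.851). Mast cell markers had 1 of 8 up and 4 down (adjusted p = 0.166), with Cma1 (-1.25 ± 0.14 SE) and Mcpt4 (-1.13 ± 0.09) down. Neutrophil markers had 3 of 7 up and 1 down (adjusted p = 0.354), with S100a9 up (1.89 ± 0.21). T and NK cell markers had 2 of 16 each way (adjusted p = 0.609), and B cell markers 3 of 9 up and 2 down (adjusted p = 0.747) with a median of 0.09 and a mean of -0.21. Skeletal muscle markers had 1 of 10 up and 3 down (adjusted p = 0.841), cell cycle genes 2 of 26 up and 6 down (adjusted p = 0.715), unfolded protein response genes 5 of 22 up and 1 down (adjusted p = 0.397), and antioxidant and glutathione genes 16 of 32 up and 9 down (adjusted p = 0.0860). Adjusted over the list alone, smooth muscle and pericyte markers had 1 up and 2 down, T and NK cell markers 2 down, cell cycle genes 2 up and 4 down, and unfolded protein response genes 3 up and 1 down. Median, mean and test differed in sign for cell cycle genes (median 0.01, mean -0.05), for smooth muscle and pericyte markers (median 0.10, mean -0.00, test down) and for the B cell markers, whose test direction was up. With slide as a block the mean of the smooth muscle and pericyte markers read -0.26. That of the unfolded protein response genes read -0.05, against 0.12 on all arrays. Over all lists, 13 passed by camera in the planned fit and 16 without the arrays with tract transcripts. All 4 red blood cell genes measured rose, with a median of 0.66, a number too small for a group test. With slide as a block none of them passed, and Hbb-bt (0.61 ± 0.26 SE on all arrays) read below 0 on each of the 3 slides that held both groups, at -0.82 to -0.15.

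Transcripts of the male tract were high on a few arrays. The epididymis and seminal vesicle markers Pate4 (2.96 ± 1.09 SE), Svs4 (2.50 ± 1.06) and Svs2 (2.09 ± 0.81) were 3 of 7 that rose, and none fell (adjusted p = 0.233 as a group). Their rise came from arrays HF-DR 7, 8 and 9, and adjusted over the list alone 2 rose. The median log2 ratio of 5 seminal vesicle genes was 6.04 on HF-DR 8, 5.42 on HF-DR 9, -0.49 on HF-DR 7 and -2.85 on t0 6, and at most -3.93 on all other arrays. Epithelial, epididymal and sperm genes had a median of 2.88 on HF-AL 7, 2.54 on HF-AL 9 and 1.46 on HF-AL 5, and at most 0.25 elsewhere. Of 8 testis and sperm markers, Tekt1, a protein of cilia and sperm tails, rose (1.79 ± 0.46) and the sperm protamine Prm2 fell (-0.76 ± 0.33), without a shift as a group (adjusted p = 0.930, median -0.09, test up). Adjusted over the list alone, Tekt1 rose and none fell. The higher Tekt1 in HF-DR did not rest on a few arrays. Fitted without the specks, Tekt1 read 0.66 to 2.11 on the HF-DR arrays other than HF-DR 8 (-0.07). It read -2.23 to -1.34 on the HF-AL arrays other than HF-AL 5, 7 and 9 (1.60, 2.48 and 2.65). None of these 5 genes passed with slide as a block, where Pate4 read 1.22, Svs4 0.59, Svs2 0.55, Tekt1 1.56 and Prm2 -0.59.

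**Figure D2:**
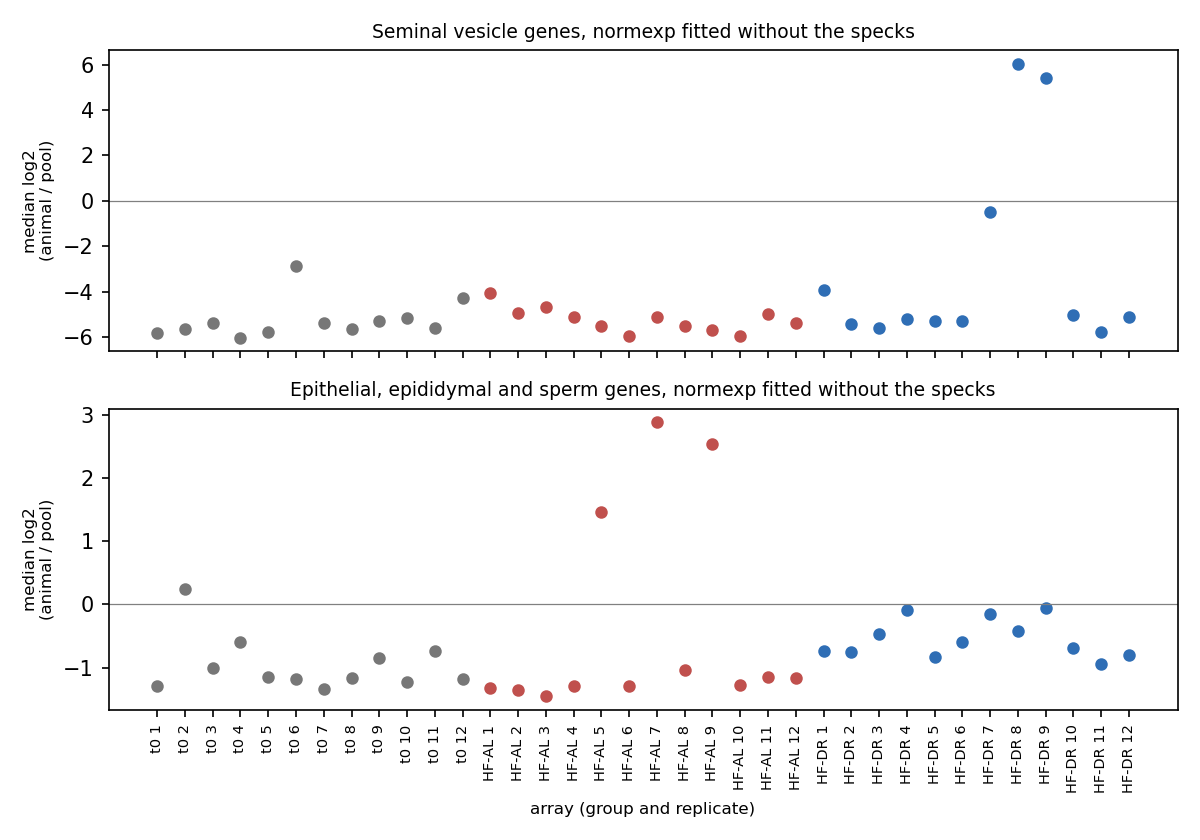
Median log2 ratio to the pool per array of 5 seminal vesicle genes (upper panel) and of 12 epithelial, epididymal and sperm genes (lower panel), with normexp fitted without the specks. HF-DR 8 (6.04) and HF-DR 9 (5.42) stand apart above, and HF-AL 7 (2.88), HF-AL 9 (2.54) and HF-AL 5 (1.46) below.

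Between HF-DR and HF-AL 10050 genes changed, 4348 up and 5702 down (5169 up and 4649 down with the authors' series matrix), and 1067 of those up and 1347 of those down changed at least 1.5-fold. With slide as a block 6574 genes changed, and on the 3 slides that held both groups the mean of the fatty acid synthesis genes was 1.79 to 1.93 (1.92 with the block) and that of the matrix genes -0.97 to -0.71 (-0.89 with the block). The background correction planned for the arrays failed on 10 of them, where specks inflated its spread. With the correction fitted without the specks 10685 genes changed, 9935 of them shared, and folds of dim genes were larger, as for Itgax (-0.69 in place of -0.52).

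The comparison of HF-AL with t0 asks what changes over 12 more weeks of ad libitum feeding. The HF-AL mice were also 12 weeks older, and feeding and age cannot be told apart here. Few genes differed, and the differences were small. Csprs, a gene of the Sp100-related repeat cluster, was 1.82-fold higher in HF-AL (log2 difference 0.87 ± 0.11 SE, n = 12 per group, limma, adjusted p = 1.2e-05). Transcripts of mast cells, the immune cells that store histamine and proteases, were higher after the 12 weeks: Mcpt4 by 0.55 ± 0.09 (adjusted p = 0.00253) and Cma1 by 0.61 ± 0.14 (adjusted p = 0.0327, and 0.0827 with slide as a block). Fam13a, an adipose gene linked to fat distribution, was lower (log2 difference -0.80 ± 0.18, adjusted p = 0.0260), at -0.82 ± 0.47 (SD, n = 12) in HF-AL and -0.02 ± 0.49 (SD, n = 12) in t0.

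Among genes with a curated name the largest rise in HF-AL was that of the immunoglobulin heavy chain Igh (1.41 ± 0.34 SE, adjusted p = 0.0440, and 0.0640 without the specks). Slc35g1 (0.83 ± 0.19), the myosin Myh14 (0.74 ± 0.12), the microtubule gene Mapt (0.72 ± 0.12), the scavenger receptor Cd163l1 (0.72 ± 0.11) and the Wnt target Axin2 (0.61 ± 0.14) also rose, with adjusted p of at most 0.0327. Angptl8 rose by 0.42 ± 0.10 (adjusted p = 0.0446), but read -1.09 with ratios scaled between arrays. The falls included the transcriptional regulator Cited2 (-0.65 ± 0.15), the macrophage elastase Mmp12 (-0.54 ± 0.10), Txnip (-0.53 ± 0.10), Adcyap1r1 (-0.49 ± 0.10), Rgs1 (-0.46 ± 0.11), the adiponectin receptor Adipor2 (-0.41 ± 0.10) and Ppp1r13l (-0.35 ± 0.08), with adjusted p of at most 0.0478. Without the specks Axin2 (adjusted p = 0.0574), Adipor2 (adjusted p = 0.0650) and Angptl8 (adjusted p = 0.107) no longer passed. Igh (1.71), Rgs1 (-0.43) and Ppp1r13l (-0.30) kept their sign with slide as a block but did not pass. Leptin did not differ beyond its spread (0.35 ± 0.23, adjusted p = 0.512).

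Mast cell markers had 2 of 8 genes up (4 adjusted over the list alone), with a median of 0.37 (camera with a preset correlation, adjusted p = 2.1e-06, and adjusted p = 0.130 with an estimated correlation). Their mean was above 0 on each of the 9 slides that held both groups, at 0.05 to 1.03 (0.35 with slide as a block). The 4 red blood cell genes, too few for a group test, had a median of 0.55, and none passed alone (3 up adjusted over the list alone). The 22 cholesterol synthesis genes had a median of 0.13 (adjusted p = 0.00539, and adjusted p = 0.685 with an estimated correlation) and none passed alone (3 up adjusted over the list alone). The 8 testis and sperm markers had a median of 0.34 (adjusted p = 0.0262, and adjusted p = 0.464 with an estimated correlation), again with none passing alone (2 up adjusted over the list alone), and their adjusted p was 0.623 without the arrays that held tract transcripts and 0.0936 without the specks. They did not pass with slide as a block, with processed signals or with Cy5 alone. Of the 10 skeletal muscle markers, Myh1 changed among all genes tested (-0.23 ± 0.05 SE, adjusted p = 0.0311), and it did not pass without the specks (adjusted p = 0.0796) or with slide as a block. Adjusted over the list alone, 1 of them rose and 1 fell.

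Other lists shifted down by small amounts in HF-AL relative to the other genes tested, which is what camera compares. The median of all genes was itself 0.018 in this comparison, and 0.006 without the specks. The 36 matrix genes had a median of -0.18 (adjusted p = 2.0e-10, and adjusted p = 0.244 with an estimated correlation), with 0 down alone and 4 down adjusted over the list alone. Their mean was below 0 on 7 of 9 slides (-0.20 with slide as a block). The 28 macrophage markers had a median of -0.10 (adjusted p = 6.7e-07, and adjusted p = 0.480 with an estimated correlation), and 1 of them, Mmp12, fell. The 19 lipolysis genes had a median of -0.20 (adjusted p = 6.3e-06, and adjusted p = 0.379 with an estimated correlation), and their mean was below 0 on all 9 slides. The 19 mature adipocyte markers had a median of -0.16 (adjusted p = 0.000179, and adjusted p = 0.603 with an estimated correlation). None of their genes passed alone, and adjusted over the list alone lipolysis had 1 up and 2 down and the adipocyte markers 1 down. The adipocyte markers did not pass with Cy5 alone. Triglyceride genes had a median of -0.15 (adjusted p = 0.00161, and adjusted p = 0.650 with an estimated correlation) and glucocorticoid-responsive genes of -0.13 (adjusted p = 0.00788, and adjusted p = 0.268 with an estimated correlation). None of these genes passed alone, and adjusted over the list alone triglyceride genes had 1 up and 1 down and glucocorticoid-responsive genes 1 down. The adipocyte markers share Plin1, Plin4, Fabp4, Cidec, Lpl, Acsl1 and Gpd1 with the triglyceride genes. They share Lipe, Aqp7, Adrb3 and Pnpla2 with the lipolysis genes. The shifts of these lists are therefore not independent of each other.

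Smaller medians passed for 6 further lists in HF-AL, with no gene passing alone or adjusted over the list alone. Cell cycle genes stood at -0.09 (adjusted p = 0.00151, and adjusted p = 0.650 with an estimated correlation) and T and NK cell markers at -0.07 (adjusted p = 0.00166, and adjusted p = 0.415 with an estimated correlation). Fatty acid oxidation genes stood at -0.07 (adjusted p = 0.00267, and adjusted p = 0.685 with an estimated correlation) and tricarboxylic acid cycle genes at -0.07 (adjusted p = 0.00570, and adjusted p = 0.731 with an estimated correlation). Branched-chain amino acid genes stood at -0.06 (adjusted p = 0.0136, and adjusted p = 0.712 with an estimated correlation) and respiratory chain genes at -0.02 (adjusted p = 0.0279, and adjusted p = 0.822 with an estimated correlation, and 0.323 without the specks). Of these 6 lists, fatty acid oxidation, tricarboxylic acid cycle, branched-chain amino acid and respiratory chain genes no longer passed without the arrays that held tract transcripts. Cell cycle genes did not pass with slide as a block, respiratory chain genes with processed signals or Cy5 alone, and tricarboxylic acid cycle genes with processed signals. By fry, which asks only whether a list moves 1 way on balance, mast cell markers (adjusted p = 8.6e-05) and testis and sperm markers (adjusted p = 0.0290) were the 2 lists that passed. Median, mean and test differed in sign for chemokines (median -0.02, mean 0.05) and for preadipocyte and fibroblast markers (median 0.00, mean 0.02, test down).

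Between HF-AL and t0 85 genes changed, 71 up and 14 down (52 up and 66 down with the authors' series matrix), and 11 of those up and 2 of those down changed at least 1.5-fold. With slide as a block 122 genes changed (45 shared), without the specks 113 (59 shared), and without the arrays that held tract transcripts 217 (66 shared).

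**Figure D3:**
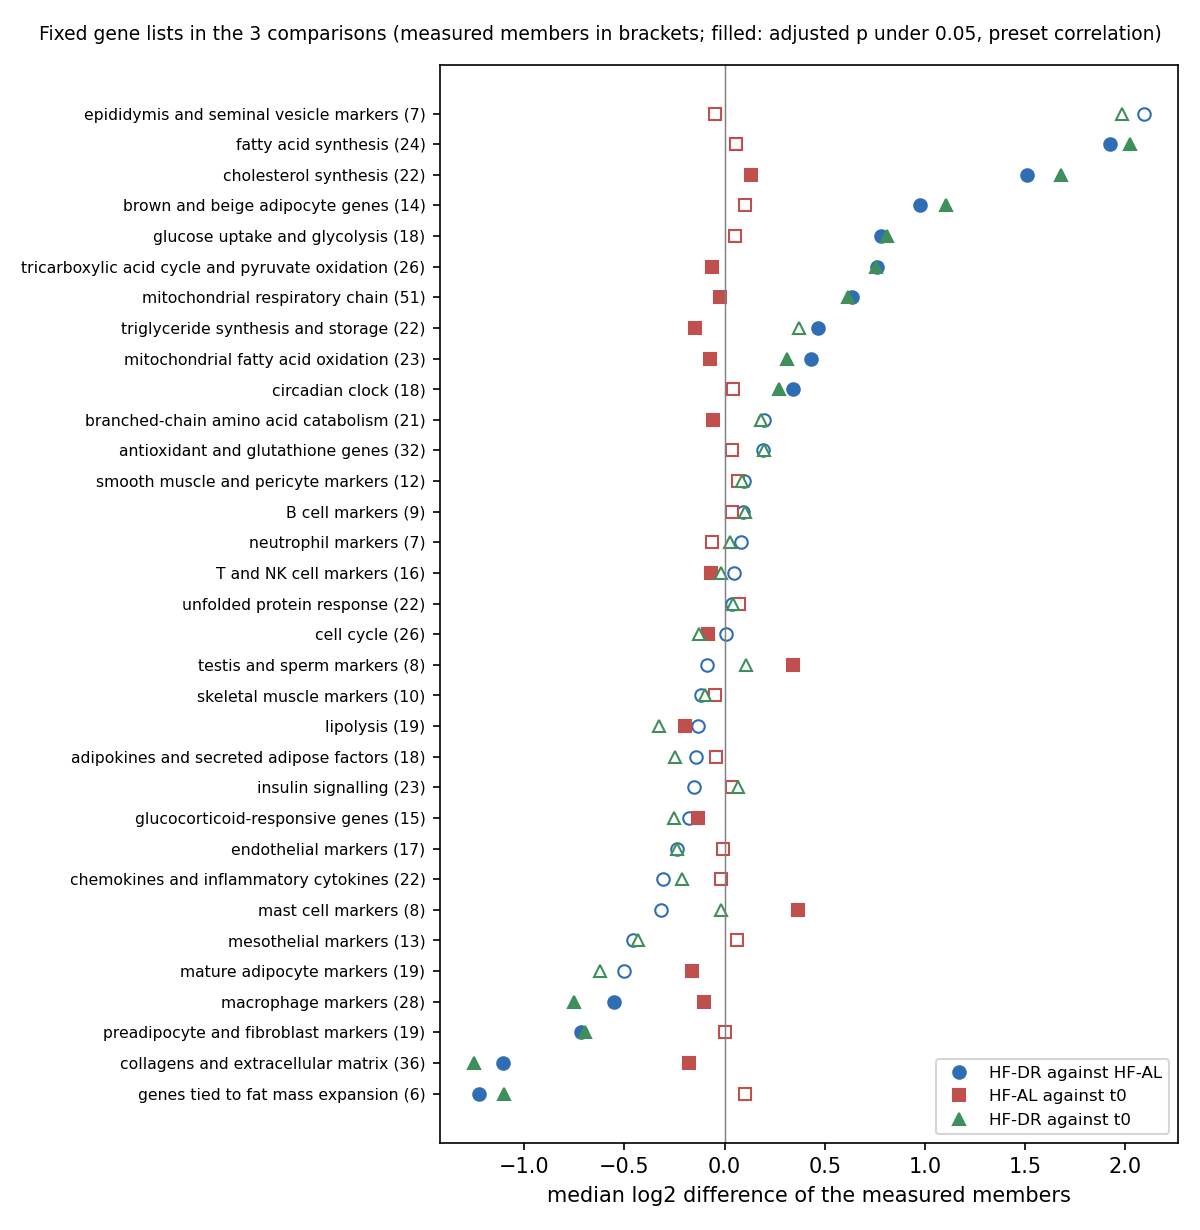
Median log2 difference of the measured genes of each list in the 3 comparisons (number of genes in brackets, filled symbols for adjusted p under 0.05 by camera with a preset correlation). Fatty acid synthesis stands at 1.92 and 2.03 in both comparisons with HF-DR and at 0.05 between HF-AL and t0, and the matrix genes at -1.11, -1.25 and -0.18.

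The comparison of HF-DR with t0 asks how restricted mice differed from mice at the start of the 12 weeks. The HF-DR mice were also 12 weeks older, so restriction and age cannot be told apart in this comparison alone. The differences from t0 were much like those from HF-AL. Elovl6 was 39.5-fold higher than in t0 (log2 difference 5.31 ± 0.15 SE, n = 12 per group, limma, adjusted p = 3.8e-25) and Ifi27 13.2-fold lower (-3.73 ± 0.14, adjusted p = 9.7e-22). Slc2a5 rose 34.5-fold (5.11 ± 0.26, adjusted p = 3.7e-18), at 2.42 ± 0.51 (SD, n = 12) in HF-DR and -2.69 ± 0.48 (SD, n = 12) in t0. Elovl3 (4.38 ± 0.24 SE), Cidea (3.78 ± 0.18), Ppp1r3b (3.72 ± 0.19), Angptl8 (3.58 ± 0.10) and the transposase-derived gene Pgbd5 (11.3-fold) followed among the rises. Ifi27l2a (-3.43 ± 0.16), Npr3 (-3.09 ± 0.23), Wfdc21 (-3.04 ± 0.21), the matrix protein thrombospondin Thbs1 (-3.01 ± 0.30), Plagl1 (8.01-fold lower), Angptl4 (-2.99 ± 0.13) and Sncg (-2.88 ± 0.14) followed among the falls.

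Against t0, 22 of 24 fatty acid synthesis genes rose, with a median of 2.03 (adjusted p = 1.8e-16, and adjusted p = 0.130 with an estimated correlation), led by Elovl6 and Acly (3.48 ± 0.17 SE). Cholesterol synthesis had 20 of 22 up at a median of 1.68 (adjusted p = 2.8e-15, and adjusted p = 0.130 with an estimated correlation), with Sqle at 2.92 ± 0.13. Tricarboxylic acid cycle genes had 25 of 26 up and 1 down at a median of 0.76 (adjusted p = 3.3e-12, and adjusted p = 0.244 with an estimated correlation). Respiratory chain genes had 48 of 51 up at 0.61 (adjusted p = 7.9e-17, and adjusted p = 0.244 with an estimated correlation). Glycolysis genes had 16 of 18 up and 1 down at 0.81 (adjusted p = 5.8e-08, and adjusted p = 0.133 with an estimated correlation). Fatty acid oxidation genes had 15 of 23 up and 1 down at 0.31 (adjusted p = 0.00470, and adjusted p = 0.685 with an estimated correlation). Brown and beige adipocyte genes had 10 of 14 up and 3 down at 1.10 (adjusted p = 0.000179, and adjusted p = 0.244 with an estimated correlation), with Cox8b at 2.59 ± 0.18. Clock genes had 10 of 18 up and 2 down at 0.27 (adjusted p = 0.0407, and adjusted p = 0.590 with an estimated correlation, and 0.0552 without the specks). The counts of these 8 lists were also the same adjusted over the list alone.

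Matrix genes fell against t0 in 32 of 36 cases, with a median of -1.25 (adjusted p = 3.2e-15, and adjusted p = 0.133 with an estimated correlation), Col3a1 by -2.42 ± 0.11 (SE). Fibroblast markers fell in 16 of 19 cases at a median of -0.70 (adjusted p = 2.9e-06, and adjusted p = 0.133 with an estimated correlation). Macrophage markers fell in 23 of 28 cases at -0.75 (adjusted p = 3.7e-07, and adjusted p = 0.467 with an estimated correlation), Lyz2 by -1.71 ± 0.14. Genes of fat mass expansion fell in 5 of 6 cases at -1.10 (adjusted p = 0.0279, and adjusted p = 0.514 with an estimated correlation, and 0.117 with slide as a block). Triglyceride genes (11 of 22 up and 6 down, adjusted p = 0.0846), mature adipocyte markers (3 of 19 up and 12 down, adjusted p = 0.0573) and endothelial markers (2 of 17 up and 11 down, adjusted p = 0.0536) did not pass as groups. Nor did mast cell markers, with 3 of 8 up and 4 down (adjusted p = 0.747): Cma1 (-0.64 ± 0.14) and Mcpt4 (-0.58 ± 0.09) fell while Kit rose (0.52 ± 0.11). These values are by camera. By fry triglyceride genes (adjusted p = 0.00179, up), mature adipocyte markers (0.00264, down) and endothelial markers (0.00499, down) passed. The 4 red blood cell genes rose, with a median of 1.17. Adjusted over the list alone, triglyceride genes had 12 up and 6 down and the counts of the other 7 tested lists were the same. Median, mean and test differed in sign for insulin signalling (median 0.06, mean -0.11), for the B cell markers (median 0.10, mean -0.06) and for smooth muscle and pericyte markers (median 0.09, mean 0.10, test down).

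Between HF-DR and t0 9627 genes changed, 4553 up and 5074 down (4774 up and 4640 down with the authors' series matrix), and 1209 of those up and 1235 of those down changed at least 1.5-fold. With slide as a block 7829 genes changed, and on the 6 slides that held both groups the mean of each shifted list kept its sign, except that of the fat mass genes on 1 slide. Without the specks 10198 genes changed, 9489 of them shared.

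Comparisons that share a group are related through it. Across genes, which are not independent replicates, the differences of HF-DR from HF-AL and from t0 correlated at r = 0.954, against 0.552 in simulated data where only the shared group related them. With the shared animals split between both comparisons r was 0.945 and 0.929, and the covariance was 0.226 against 0.00644 from the shared group. Of the genes changed in each, 3885 rose in both and 4575 fell in both. Independent comparisons would give 1200 and 1753, numbers that leave out the shared group and so understate what sharing alone gives. The differences of HF-DR from HF-AL and of HF-AL from t0 correlated at r = -0.0437 (simulated -0.485, splits 0.112 and 0.148, covariance -0.0031 against -0.0054). The differences of HF-AL and of HF-DR from t0 correlated at r = 0.258 (simulated 0.462, splits 0.268 and 0.107, covariance 0.0189 against 0.00507). Here 42 genes rose in both (19.6 if independent) and 13 fell in both (4.31 if independent). The covariance was above that from sharing and r stayed above 0 when no t0 animal was shared, while the simulated r, from data without differences between groups, was higher.

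Whether HF-DR moved genes against their course from t0 to HF-AL was examined with separate HF-AL animals. Genes called between HF-AL and t0 were chosen with 1 set of HF-AL replicate numbers. Their direction between HF-DR and HF-AL was read with the other set of HF-AL arrays. Only HF-AL was split, and all t0 and HF-DR arrays entered both fits. With the choice in odd-numbered replicates, 874 genes were called, 841 up and 33 down, and 428 moved the opposite way, 49.0% (exact Clopper-Pearson 95% interval 45.6% to 52.3%). With the choice in even-numbered replicates, 10 genes were called and 7 moved the opposite way, 70.0% (exact 95% interval 34.8% to 93.3%). Genes are not independent replicates, and the odd-numbered set held the HF-AL arrays 5, 7 and 9 with tract transcripts. Without the specks the shares were 62.3% of 618 genes and 62.2% of 45, and with processed signals 73.7% of 76 and 84.6% of 13. With sets of replicates 1 to 6 and 7 to 12 the numbers of genes called were 63 and 10, and the shares 46.0% and 70.0%. No share expected from all genes was computed, and between HF-DR and HF-AL falls (5702) outnumbered rises (4348).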

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

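The tests of tissue, diet, further feeding, carry-over and failed background fits were chosen only after the result was seen, and the tests of other splits of the arrays and of the Cy3 channel were planned before.

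Transcripts of the epididymis and sperm stood out on single arrays although their genes did not pass the signal filter and entered no comparison. Adam7, a gene of the epididymis, read 3.01 on HF-AL 9, where the highest t0 array read 0.97. Smcp, a gene of the sperm tail, read 2.36 on HF-AL 7 (highest t0 array 0.00), and Ldhc, a lactate dehydrogenase of sperm, read 3.10 on HF-AL 7 (highest t0 array -0.55). A t0 array stood out too: Lcn5, another gene of the epididymis, read 2.95 on t0 11 and at most -0.22 on the other arrays. All are log2 ratios to the pool, fitted without the specks.

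Seminal vesicle transcripts were high on HF-DR 7, 8 and 9. Of 12 HF-DR arrays 4 read above the highest HF-AL array, and 1 of these, HF-DR 1, did so at -3.93 against -4.05. The genes counted were picked for their values on HF-DR 7, 8 and 9, so this count cannot decide on a diet effect. Seminal vesicle genes not picked this way read -4.44 to -3.62 on the remaining HF-DR arrays and -4.67 to -3.96 on the HF-AL arrays. These values argue against a diet effect of the size seen on HF-DR 8 and 9 in all animals. Tissue of the seminal vesicle in those samples is a candidate explanation: other seminal vesicle genes, not used to find the pattern, differed there by a median log2 of 9.00. This rests on HF-DR 8 (5.24) and HF-DR 9 (4.90), while HF-DR 7 read -0.77, against at most -3.62 on the remaining HF-DR arrays. Signal carried over between arrays of a slide stays open, since 0 other arrays of this series lay on those slides. A diet effect in a few animals was not tested.

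Epithelial and sperm transcripts were high on HF-AL 5, 7 and 9. Of 12 HF-AL arrays 3 read above the highest t0 array. The genes counted were picked for their values on these arrays, so this count cannot decide on an effect of 12 more weeks of feeding. Motile cilia genes not picked this way had a median of -0.42 to -0.25 on the remaining HF-AL arrays and of -0.37 to 0.21 on the t0 arrays. These values argue against a rise of cilia genes with further feeding in all animals. Duct epithelium with cilia in those samples is a candidate explanation, since other genes of motile cilia differed there by a median log2 of 2.21. Without these 3 arrays and HF-DR 7, 8 and 9 the number of genes changed between HF-AL and t0 was 217 in place of 85, and the shift of the testis and sperm markers had an adjusted p of 0.623.

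Between HF-DR and HF-AL 10050 of 16500 genes differed, and 6574 with slide as a fixed block. A difference in hybridisation or scanning that also touched the pool channel, as the whole cause, is argued against. The pool was the same on every array, and in its Cy3 channel 287 genes differed, against 10050 in the ratios. The Cy3 values were quantile normalised, so a shift of a whole array would not show. Nor can the pool show a difference in the RNA, labelling or scan of the Cy5 channel. Background fits that failed on some arrays are argued against as the whole cause, since 9935 of the 10050 genes were called again with the repaired correction. Food restriction itself, and a change in the mix of cells that came with it, are consistent with these values, but the cell mix was not measured apart from the markers.

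Over 100 splits of the arrays, the real one included, only the real split called as many genes in each comparison. This argues against chance as the source of these numbers, but 100 splits cannot exclude it. The real numbers were 10050, 85 and 9627 (HF-DR against HF-AL, HF-AL against t0, HF-DR against t0), and the highest among the other splits were 6261, 1 and 2534.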

How the results depend on the processing

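The fit without the specks, the 3 sets of arrays left out and slide as a random block were chosen after seeing the data, and all other settings were planned before. The cause of the changes below was not tested unless a clause gives it.

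Between HF-DR and HF-AL the number of genes changed stayed within 1.5 times of 10050, except for 6574 with slide as a fixed block, where only slides that hold several groups inform the difference, and 2414 at 1.5-fold or more, a stricter threshold. Between HF-DR and t0 (9627) the exceptions were 5758 with ratios scaled between arrays and 2444 at 1.5-fold or more. Between HF-AL and t0 the number of 85 moved most. It was 137 with no background subtraction, 43 with processed signals, 38 with median centring, 316 with only the 2 groups compared, 443 with array weights, 217 without the arrays with tract transcripts, 56 without the arrays with an odd background, 20 at adjusted p under 0.01 and 13 at 1.5-fold or more. The replicate block gave 54, and 10008 and 9587 in the other comparisons. Arrays of the same replicate number correlated at a median of -0.03 (t0 and HF-AL), -0.06 (t0 and HF-DR) and 0.14 (HF-AL and HF-DR, 7 of 12 over 0.1), and 1, 0 and 2 of 12 were closest to their own number, so the numbers were not taken as pairs. Scan date as a block was not run, since all arrays were scanned on 1 day. Slide as a random block gave 10053, 85 and 9629, at a correlation of 0.00233.

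Leaving out each array in turn gave 9725 to 10253 genes between HF-DR and HF-AL, 49 to 151 between HF-AL and t0 and 9328 to 9772 between HF-DR and t0. The arrays that moved the number between HF-AL and t0 by more than 1.5 times were t0 5 (49 without it), t0 7, t0 9 and t0 11 (53 each), HF-AL 5 (56), HF-AL 9 (55) and HF-DR 8 (151).

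The share of changed genes that rose between HF-AL and t0 was 83.5%. It was 69.3% with no background subtraction, 72.1% with processed signals, 63.9% with Cy5 alone, 44.1% with the series matrix, 66.4% without the specks, 65.6% with slide as a fixed block and 73.4% with only the 2 groups compared. Between HF-DR and HF-AL it was 43.3%, 52.6% with the series matrix and 29.6% with median centring, which also moved the median of all genes to -0.12 there and to 0.11 between HF-AL and t0.

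With an estimated correlation 0 lists passed in any comparison, against 13, 15 and 12 with the preset one. Without the arrays with tract transcripts 10 of the 15 between HF-AL and t0 passed again, and with processed signals or Cy5 alone 12. By fry 24, 2 and 24 passed, and with no filter 19 passed between HF-DR and t0. Between HF-DR and HF-AL, against 13, more lists passed under some settings. There were 16 without the arrays with tract transcripts, 15 with slide as a fixed block (12 of them shared) and 18 with no filter. The opposed share chosen in odd replicates was 73.7% with processed signals and 62.3% without the specks, and that in even replicates 100% (3 genes) at adjusted p under 0.01.

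Among named genes whose difference passed in the planned fit or under the alternative, signs reversed in 8 cases, and differences that passed in neither also changed sign, as for Fam13a with slide as a fixed block (-0.32 to 0.02 between HF-DR and HF-AL). Between HF-DR and HF-AL the 8 included Myl9 with the series matrix (0.14), Srebf2 with the mean over probes (0.25), Slc35g1 without the arrays with tract transcripts (0.42) and, at -0.00795, Cd8b1 HF-DR against HF-AL with median centring. The difference of Adipor2 HF-DR against t0 read 0.00401 with the mean over probes. Between HF-DR and t0 Svs2 (-1.61) and Pate4 (-1.49) reversed with ratios scaled between arrays, as Angptl8 did between HF-AL and t0 (-1.09). With slide as a fixed block 29, 5 and 12 named calls were lost in the 3 comparisons, and with scaled ratios 21, 11 and 35. Signal over background limits dim genes: Mmp12 was well above background on 12 t0 arrays, 9 HF-AL arrays and 1 HF-DR array, so its ratio in HF-DR is a bound.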

Other observations

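Single genes of the neutrophil, B cell and chemokine lists passed, although between HF-DR and HF-AL these lists did not pass as groups (camera, adjusted p = 0.354, 0.747 and 0.318). Between HF-DR and HF-AL the calgranulin genes S100a9 (log2 difference 1.89 ± 0.21 SE, n = 12 per group, limma, adjusted p = 7.3e-10) and S100a8 (0.61 ± 0.10, adjusted p = 3.8e-06) rose, as did the B cell gene Ms4a1 (0.71 ± 0.22, adjusted p = 0.00496). The antibody-joining chain Jchain fell (-1.07 ± 0.28, adjusted p = 0.00106), but with slide as a block it read -0.48 and did not pass, and on the 3 slides that held both groups it ran from -1.08 to 1.07. Further, the chemokine Ccl8, which did not pass there (0.66 ± 0.32, adjusted p = 0.0700), rose against t0 (1.32 ± 0.32, adjusted p = 0.000514). On 1 array, t0 1, the T cell gene Cd3d read 1.20.

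Single genes also passed from lists that did not pass as groups by camera between HF-DR and HF-AL. These were the antioxidant and glutathione genes (adjusted p = 0.0860, and 0.685 with an estimated correlation) and the skeletal muscle markers (adjusted p = 0.841). The mitochondrial peroxiredoxin Prdx3 (0.96 ± 0.08 SE, adjusted p = 4.1e-13) and the sulfiredoxin Srxn1 (0.82 ± 0.08, adjusted p = 3.5e-11) rose, and the glutathione peroxidase Gpx1 fell (-1.29 ± 0.08, adjusted p = 1.2e-15). Myoglobin (Mb, 0.71 ± 0.11, adjusted p = 1.3e-06) rose, while the myosin and troponin genes Myh2 (-0.38 ± 0.08, adjusted p = 0.000123) and Tnni2 (-0.29 ± 0.09, adjusted p = 0.00403) fell, and with slide as a block Mb read 0.44 and Tnni2 did not pass. Tekt1, a gene of cilia and sperm, rose between HF-DR and t0 (2.76 ± 0.46, adjusted p = 3.7e-06) and read between 0.66 and 2.11 on 11 HF-DR arrays, with -0.07 on HF-DR 8. On those 11 arrays the median of other motile cilia genes read -0.35 to 0.38, against -0.37 to 0.21 on the t0 arrays. The sperm protamine Prm1 read -1.62 to -0.83 there, against -1.64 to -0.58 on the t0 arrays. No explanation of the rise of Tekt1 was tested.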
